A study of Mus musculus with 35 samples.

How the data were processed

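Gene expression was measured on 35 Affymetrix arrays, each hybridised with labelled cDNA made from total RNA of type 1 conventional dendritic cells (cDC1). The cells had been purified from mouse spleen by flow cytometric sorting. cDC1 are the dendritic cells that take up dying cells and present their antigens to CD8 T cells. Per the labels, the mice carried either wild-type Mycl or a GFP allele at Mycl on 1 or both chromosomes, or they were wild type or deficient for Mxd1. Some mice received 100 µg of poly IC, a synthetic double-stranded RNA that triggers the interferon response, 5 h (Mycl mice) or 18 h (Mxd1 mice) before the spleens were taken. The titles number the Mycl arrays as sets 1, 2 and 3. Set 1 held 5 heterozygous and 4 homozygous Mycl mutant (KO) arrays at steady state. Set 2 held 5 wild-type (WT) and 5 Mycl KO arrays at steady state, and set 3 held 5 WT and 5 Mycl KO arrays after poly IC. The Mxd1 set held 3 WT arrays and 3 labelled Mxd1 KO after poly IC. The labels call the arrays of a group biological replicates and do not say whether each is a different mouse.

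The deposited table gives log2 values for 35556 transcript clusters on each array. Per the submitters' processing notes, the authors used the Affymetrix Expression Console with RMA, which corrects the background, equalises the distribution of values between arrays and summarises the probes of each cluster. Versions are not given in the sources used here. Array medians were 6.50 to 6.57 in set 1, 5.55 to 5.60 in set 2, 5.47 to 5.53 in set 3 and 5.95 to 6.01 in the Mxd1 set. Pairs of arrays of 1 set shared 1987.08, 14.69, 13.62 and 30.8 exactly equal values on average in these sets, against 0.07 to 0.27 for pairs from different sets. The 4 sets were therefore treated as normalized separately, and every test was made within a set or between differences that were each taken within a set. The planned tests of poly IC against steady state, which set array levels of set 3 against those of set 2, were not made, and those levels are given as values only. The design names spike-ins added by cell count, and no such features were found in the table. RMA values without them cannot show a change in total RNA per cell, so every fold change and list shift is relative to the other transcripts of the array. No 2 arrays held identical values.

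Clusters were named through the platform annotation. Of the 35556 clusters, 21789 had 1 gene symbol, 1621 had several and 12146 were not listed in the annotation used here. For 21698 of the clusters with 1 symbol the Entrez identifier was found in the RefSeq gene table of GRCm38.p6, and 0 symbols had to be updated. The 21789 clusters gave 19938 genes, and for the 999 genes with several clusters the cluster with the highest mean level over the 35 arrays was used. A gene entered a comparison if its value was at or above the 30th percentile of the named clusters in at least as many arrays as the smaller group holds.

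Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Only the groups compared entered each fit. The comparisons were Mycl KO against heterozygous cells in set 1, Mycl KO against WT cells in sets 2 and 3, and libraries labelled Mxd1 KO against WT libraries. Further fits gave the Mycl KO effect over both steady-state sets with the set as a block, the difference between the Mycl KO effects of sets 1 and 2, and the difference between those of sets 3 and 2. Log2 fold changes are KO minus control and are given with their standard error (SE) from the fit, group levels with their standard deviation (SD).

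A total of 27 gene lists were tested with camera at its preset correlation of 0.01, again with a correlation estimated from the data, and with fry, each adjusted over the 27 lists of a comparison. The lists cover ribosome biogenesis, MYC target core genes, the MYC and MAX network, cytosolic ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, nucleotide and one-carbon synthesis, glycolysis, oxidative phosphorylation, mitochondrial translation, cell cycle and DNA replication, the type I interferon response, dendritic cell maturation, antigen presentation, cDC1 identity, cholesterol synthesis, the unfolded protein response and chaperones, the ATF4 stress response, apoptosis and survival, and immediate early genes of dissociation stress. Further lists hold markers of cDC2, plasmacytoid dendritic cells, monocytes and macrophages, neutrophils, B cells, T and natural killer (NK) cells and erythroid cells. Some genes stand in more than 1 list. No list call at the preset correlation was kept at an adjusted p under 0.05 with the estimated correlation in any comparison. Fry called 8 lists in set 1, 6 in set 2, 5 in set 3, 11 over both steady-state sets, and 0 in the Mxd1 set and for either difference between KO effects. Its calls included ribosome biogenesis in sets 1 and 2 and cytosolic ribosomal proteins in sets 2 and 3, and left out ribosome biogenesis, maturation and interferon genes in set 3. A list score is the mean log2 level of the members on an array minus the median of that array. Libraries standing apart from groups of 4 or 5 were looked for with Dixon's test on the list scores and the levels of the targeted genes.

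Dixon's test and the adjustment over the members of a list alone were not in the written plan. The groups, the other tests of the comparisons and lists, the gene lists, filters and the rule for naming genes were fixed before the data were examined. By that rule the text names Mycl and Mxd1, the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold in each comparison, leaving out predicted genes without a proper symbol. It also names the 2 members of each list with the largest change past the threshold (or, where none passed, the member with the smallest p), and the MYC and MAX network. Under poly IC against steady state the genes with the largest differences are named. Nkg7 and the genes near Mycl were named outside these rules, for tests chosen after the result was seen.

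The fits were tested on simulated data in which 200 genes of each comparison were changed by known amounts. Of the genes changed by 0.5 on the log2 scale, 91.0% were recovered in set 1, 89.6% in set 2, 65.7% in set 3 and 38.8% in the Mxd1 set, and of those changed by 1, 98.5%, 98.5%, 91.0% and 88.1%. Of the genes called, 3.72% to 6.71% were false across the 7 fits. The simulated noise was independent between genes, while real libraries can shift many genes together. The recovered and false shares may therefore not hold for the real data. The alternatives tried were no filter on dim genes, a filter at the 50th percentile, the mean of all clusters of a gene, quantile normalization of all 35 arrays, centring on array medians, all 8 groups in 1 fit, a trended and robust prior, array weights, a 1.5-fold minimum, the replicate number as a block, and leaving out each array in turn. The planned centring on spike-in or other control features was not run. Leaving out libraries of set 3 with low interferon scores or high Mycl, and an interferon score as a covariate, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.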

Results

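The arrays compared cDC1 of mouse spleen that, per the labels, lacked Mycl, the MYC family transcription factor of dendritic cells, or Mxd1, a partner of MAX that represses genes bound by MYC proteins, with control cells. The comparisons address what each factor changes in resting cDC1 (Mycl) and in cDC1 taken after poly IC (Mycl and Mxd1). Mycl transcripts were low in the Mycl KO groups. In set 1 the log2 level was 6.96 ± 0.16 (SD, n = 4) in KO and 9.84 ± 0.11 (n = 5) in heterozygous cells, and in set 2 it was 5.65 ± 0.14 in KO and 9.67 ± 0.11 in WT cells (n = 5 each). In set 3, under poly IC, it was 9.43 ± 0.31 in WT cells and 6.47 ± 1.36 in KO cells. The spread in KO cells came from library 3, at 8.87, while the other 4 KO libraries lay between 5.52 and 6.14. Mxd1 in the Mxd1 set was 10.51 ± 0.11 in KO and 10.82 ± 0.20 in WT cells (n = 3 each), a difference of -0.31 ± 0.11 (SE) that did not pass limma's test (adjusted p = 0.260). This level does not support the KO label of these libraries. Whether the Mxd1 probes lie outside the deleted part was not tested, so the label stays unchecked and they are called libraries labelled Mxd1 KO.

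**Figure D1:**
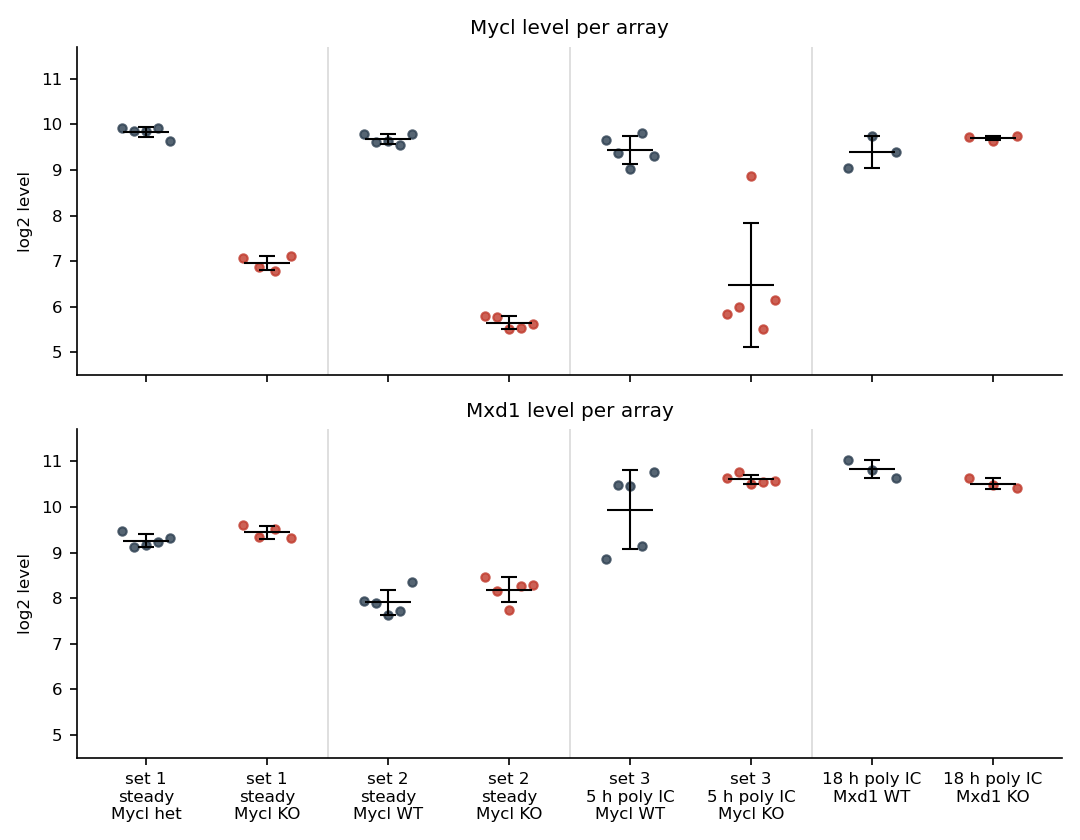
Log2 levels of Mycl (top) and Mxd1 (bottom) on each of the 35 arrays by group, with horizontal bars for the group mean and error bars for the SD. Mycl lies at 5.52 to 6.14 in 4 of the 5 Mycl KO libraries of set 3 and at 8.87 in library 3, and levels of different sets were normalized separately.

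In set 1 at steady state, transcripts of the machinery that makes ribosomes lay lower in Mycl KO than in heterozygous cells. Wdr75, a nucleolar protein of the small subunit processome, fell by 0.48 ± 0.05 (SE; adjusted p = 0.0106) and Abce1, which recycles ribosomes after termination, fell by 0.40 ± 0.05 (adjusted p = 0.0160). With Mycl itself (-2.88 ± 0.08, adjusted p = 1.3e-08) these were the 3 genes of 14023 that passed limma's test, and 1991 genes had an unadjusted p under 0.05. With all 8 groups in 1 fit neither Wdr75 (adjusted p = 0.803) nor Abce1 (0.851) passed. Wdr75 also lost its call without KO library 1 or 3 or heterozygous library 2 or 3, and Abce1 without any 1 of the KO libraries or without heterozygous library 2 or 3. Of the 60 ribosome biogenesis genes, 1 fell over all genes tested and 24 fell when adjusted over the list alone, all 60 lay below 0, and their median was -0.19 (camera adjusted p = 3.65e-24). Of the 54 MYC target core genes, which overlap with that list, 0 passed over all genes and 28 fell when adjusted over the list alone, with a median of -0.20 (camera adjusted p = 3.01e-19). An example is Nop2, a nucleolar RNA methyltransferase, at -0.40 ± 0.06 (adjusted p = 0.0680). Both list calls were lost with an estimated correlation (adjusted p = 0.236 with an estimated correlation for each).

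Genes that feed protein synthesis and growth lay lower as well in set 1, without any member passing over all genes tested. All 18 aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, lay below 0, 6 of them past the test when adjusted over the list alone (median -0.14, camera adjusted p = 1.8e-07). Of 22 genes of nucleotide and one-carbon synthesis, 21 lay below 0 and 7 passed when adjusted over the list alone, an example being Ctps, which makes CTP, at -0.47 ± 0.06 (adjusted p = 0.0601; median -0.16, camera adjusted p = 2.35e-08). Adjusted p was 0.254 with an estimated correlation for either list. Cell cycle genes had 43 of 44 members below 0, 0 of them past either adjustment (median -0.16, camera adjusted p = 8.88e-09; adjusted p = 0.405 with an estimated correlation). Cytosolic ribosomal proteins had a median of -0.06 (46 of 53 below 0; camera adjusted p = 5.07e-06), mitochondrial translation genes of -0.09 (37 of 39; 2.33e-06), translation factors of -0.09 (27 of 30; 3.31e-05) and oxidative phosphorylation genes of -0.06 (42 of 48; 0.000337). These 4 lists had 0 members past either adjustment, and their adjusted p was 0.405, 0.405, 0.405 and 0.599 with an estimated correlation. Without KO library 2 the medians of nucleotide synthesis and cytosolic ribosomal proteins were -0.10 and -0.04. The median of oxidative phosphorylation was -0.03 without KO library 2 (camera adjusted p = 0.0729), -0.10 without KO library 4, and -0.11 and -0.04 without heterozygous library 1 or 2.

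Maturation, identity and immediate early genes lay higher in the Mycl KO cells of set 1. Of 40 genes of dendritic cell maturation, such as costimulatory molecules and cytokines, 36 lay above 0, with 15 higher and 1 lower when adjusted over the list alone and 0 over all genes tested (median 0.17, camera adjusted p = 8.26e-10). Marcksl1, an actin-binding protein of this list, was at 0.20 ± 0.05 (adjusted p = 0.182). Of 27 cDC1 identity genes, 25 lay above 0 and 3 were higher when adjusted over the list alone (median 0.12, camera adjusted p = 4.24e-07), with Gcsam at 0.30 ± 0.06 (adjusted p = 0.108). Of 25 immediate early genes, which also respond to tissue dissociation, 22 lay above 0 and 9 were higher when adjusted over the list alone (median 0.18, camera adjusted p = 1.4e-08). The adjusted p of these 3 lists was 0.236 with an estimated correlation. Antigen presentation genes had a median of 0.08 (19 of 24 above 0; camera adjusted p = 0.0102), with an adjusted p of 0.405 with an estimated correlation. Without heterozygous library 5 that median was 0.04 and the call was lost (camera adjusted p = 0.148). The count of 3 genes was 1 without KO library 1 or 3 or without heterozygous library 2 or 3, 5 without heterozygous library 1 and 7 without heterozygous library 5. With array weights it was 141, of which 41 were higher and 100 lower, and after quantile normalization of all arrays it was 6, of which 1 was higher and 5 lower.

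In set 2 at steady state, 861 of 14012 genes passed limma's test between Mycl KO and WT cells, 530 higher and 331 lower, of which 65 differed by at least 1.5-fold (40 higher, 25 lower). Myc, the founding member of the MYC family, rose by 1.18 ± 0.11 (adjusted p = 7.85e-05), from 7.54 ± 0.25 (SD) to 8.72 ± 0.20 (n = 5 each). Ccnd2, the G1 cyclin D2, rose by 1.04 ± 0.14 (adjusted p = 0.000664), and Bcl2, which blocks apoptosis, by 0.63 ± 0.07 (adjusted p = 0.000226). The largest falls after Mycl (-4.03 ± 0.07, adjusted p = 1.07e-14) were Adgrf5, an adhesion receptor (-1.44 ± 0.17), Cd14, the coreceptor for bacterial lipopolysaccharide (-1.42 ± 0.10), and Ndufs5, a subunit of respiratory complex I (-1.21 ± 0.13). Slc25a33, a mitochondrial pyrimidine nucleotide carrier, fell by 0.88 ± 0.18, Tssc4 by 0.84 ± 0.11, the kinase Stk38l by 0.76 ± 0.17 and the transcription factor Crem by 0.69 ± 0.12. Among the further large rises were the lectin Cd209a (1.37 ± 0.25), the glycoprotein Emb (1.17 ± 0.16), the neuronal RNA-binding protein Elavl4 (1.11 ± 0.08), the lymphocyte adhesion receptor Cd226 (0.97 ± 0.11), the killer cell receptor Klrd1 (0.97 ± 0.17) and the Ral regulator Rgl1 (0.96 ± 0.21). The adjusted p of the 13 genes without a p beside them ranged from 1.72e-06 to 0.0177. Elavl4 was at 4.02 ± 0.13 (SD) in WT cells, below the filter level of those arrays, so the size of its rise is not exact.

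**Figure D2:**
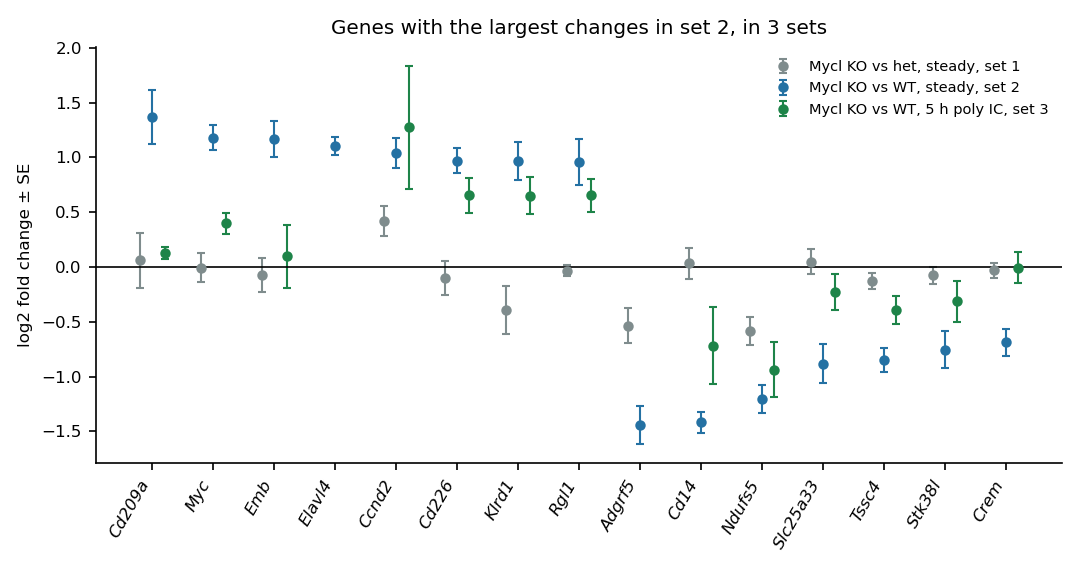
Log2 fold changes ± SE, Mycl KO minus control, of the 15 genes other than Mycl with the largest changes in set 2, in sets 1, 2 and 3; a missing point means that the gene was below the filter in that set. Myc was at 1.18 in set 2, -0.01 in set 1 and 0.40 in set 3.

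Genes of protein synthesis lay mostly lower in set 2. Of 60 ribosome biogenesis genes, 10 fell and 1 rose over all genes tested, and 17 fell and 1 rose when adjusted over the list alone (median -0.10, camera adjusted p = 1.01e-07). Gtpbp4, a GTPase of the large subunit precursor, fell by 0.53 ± 0.07 (adjusted p = 0.000790) and Polr1c, a subunit of RNA polymerases I and III, by 0.50 ± 0.06 (adjusted p = 0.000586). All 53 cytosolic ribosomal proteins lay below 0, of which 4 fell over all genes and 19 when adjusted over the list alone (median -0.13, camera adjusted p = 5.02e-15), with Rps3 at -0.35 ± 0.06 and Rps15a at -0.32 ± 0.09. Translation factors fell in 7 of 30 cases, and in 13 when adjusted over the list alone (median -0.11, camera adjusted p = 1.01e-07), with Eef1e1 at -0.41 ± 0.07 and Eef1b2 at -0.36 ± 0.07. Of 18 aminoacyl-tRNA synthetases 5 fell, 6 when adjusted over the list alone, with Tars at -0.44 ± 0.05 and Lars at -0.25 ± 0.06 (median -0.13, camera adjusted p = 0.000149). The adjusted p was 0.263, 0.263, 0.186 and 0.263 for these 4 lists with an estimated correlation.

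The MYC target core genes of set 2 held 9 falls and 2 rises, 15 and 4 when adjusted over the list alone (median -0.07, camera adjusted p = 0.000945; adjusted p = 0.425 with an estimated correlation). Nip7, a ribosome assembly factor, fell by 0.47 ± 0.07 and the mitochondrial chaperonin Hspd1 by 0.43 ± 0.11. Of 22 genes of nucleotide and one-carbon synthesis, 3 fell and 0 rose, 5 falls when adjusted over the list alone, with Uck2 at -0.46 ± 0.11 and Ctps at -0.31 ± 0.07. The list as a whole did not pass camera (median -0.03, adjusted p = 0.227). Oxidative phosphorylation genes had 1 fall, Atp5d (-0.23 ± 0.06), and 0 when adjusted over the list alone (median -0.06, camera adjusted p = 0.000364; adjusted p = 0.565 with an estimated correlation). Their median was -0.09 without KO library 3 and -0.04 without KO library 4. Among 39 genes of mitochondrial translation Mrpl17 fell by 0.26 ± 0.05, also the 1 call when adjusted over the list alone (median -0.03, camera adjusted p = 0.109). Of the MYC and MAX network, Myc alone of 11 genes passed, over all genes and over the list alone (camera adjusted p = 0.874, with a median of -0.00379 and a mean of 0.07), and the others ranged from -0.15 ± 0.07 (Mga) to 0.06 ± 0.05 (Mnt). Mxd1 was at 0.28 ± 0.13 (adjusted p = 0.248).

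Genes of cholesterol synthesis, maturation and cDC1 identity lay mostly higher in set 2. Of 19 cholesterol synthesis genes, 5 rose and 0 fell, 9 when adjusted over the list alone (median 0.16, camera adjusted p = 7.64e-05; adjusted p = 0.425 with an estimated correlation), with Msmo1 at 0.57 ± 0.11 and Dhcr7 at 0.52 ± 0.09. Of 39 maturation genes 4 rose, among them the cytokine Tnf by 0.89 ± 0.18 (adjusted p = 0.0124) and Cd200 by 0.55 ± 0.09. In this list 11 rose and 3 fell when adjusted over the list alone (median 0.24, camera adjusted p = 0.000149; adjusted p = 0.501 with an estimated correlation). Of 27 cDC1 identity genes 7 rose and 3 fell, 11 and 3 when adjusted over the list alone (median 0.09, camera adjusted p = 0.0441; adjusted p = 0.615 with an estimated correlation). The list's named changes were the falls of Hepacam2 (-0.60 ± 0.10) and Cd8a (-0.38 ± 0.08). Type I interferon genes rose in 5 of 39 cases by either adjustment (median 0.07, camera adjusted p = 0.0143; adjusted p = 0.577 with an estimated correlation), with Irf7 and Cmpk2 at 0.43 each. Cell cycle genes rose in 2 of 43 cases, E2f8 (0.35 ± 0.10) and Cdt1 (0.29 ± 0.07), and in 8 when adjusted over the list alone (median 0.15, camera adjusted p = 0.000149; adjusted p = 0.615 with an estimated correlation). The camera call of cDC1 identity was lost without KO library 1, 2 or 3 or WT library 3 or 4 (adjusted p = 0.108, 0.157, 0.0744, 0.0902 and 0.0810). That of interferon genes was lost without KO library 5 (median 0.04, adjusted p = 0.126), and the cell cycle median was 0.23 without KO library 4.

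Several small lists of set 2 held calls without passing camera. Of 16 glycolysis genes 2 rose and 1 fell by either adjustment, the rises being the glucose transporters Slc2a1 (0.52 ± 0.07) and Slc2a3 (0.50 ± 0.14; camera adjusted p = 0.968). Antigen presentation genes rose in 2 of 24 cases by either adjustment, Tapbpl (0.24 ± 0.06) and Tap1 (0.23 ± 0.06; camera adjusted p = 0.245). Of 19 genes of the ATF4 stress response 2 fell, 5 when adjusted over the list alone, namely Chac1 (-0.65 ± 0.10) and Slc3a2 (-0.48 ± 0.11) over all genes (camera adjusted p = 0.0583). Apoptosis and survival genes held 2 rises, Bcl2 and Mdm2 (0.25 ± 0.06), and 3 rises and 1 fall over the list alone (camera adjusted p = 0.231). Chaperones had 1 fall, Hspd1, and 1 rise and 1 fall when adjusted over the list alone (camera adjusted p = 0.402). Immediate early genes had 4 rises and 1 fall, among them Ier3 (0.73 ± 0.13), and 4 and 2 when adjusted over the list alone (camera adjusted p = 0.402).

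Transcripts that mark other spleen cells changed in both directions in set 2, with 11 rises and 5 falls among 71 markers. Markers of cDC2 held 2 rises and 1 fall among 11, with Cd209a up and Cd4 at -0.53 ± 0.07. Plasmacytoid markers held 3 rises and 1 fall among 10, with Tcf4 at 0.50 ± 0.12 and Pacsin1 at -0.54 ± 0.08. Monocyte and macrophage markers held 2 rises and 2 falls among 15, with Cx3cr1 at 0.56 ± 0.11 and Spic at -0.58 ± 0.16. B cell markers held 2 rises and 1 fall among 11, with Cd22 at 0.70 ± 0.08 and Ms4a1 at -0.58 ± 0.10. T and NK cell markers rose in 2 of 13 cases, Klrd1 and Tbx21 (0.39 ± 0.07), and neutrophil (6) and erythroid (5) markers held 0 calls in limma's test. When adjusted over the list alone, rises and falls were 5 and 2 for cDC2, 3 and 2 for plasmacytoid, 4 and 3 for monocyte, 2 and 1 for B cell and 3 and 0 for T and NK cell markers, and 0 for the last 2 lists. Camera called T and NK cell markers (adjusted p = 0.0143; adjusted p = 0.425 with an estimated correlation) and none of the other 6 lists, whose adjusted p was 0.245, 0.0583, 0.439, 0.109, 0.717 and 0.717 in the order given. The median of the T and NK list, 0.14, was 0.09 without KO library 5, 0.08 without WT library 1 and 0.21 without WT library 5. The count of 861 genes was 408 without WT library 1, 507 without WT library 2 and 452 without KO library 5, and it was 358 with all 8 groups in 1 fit. Slc2a1, Ctps and Ndufs5 lie within 40 tested genes of Mycl on its chromosome, and Ctps is also the example of nucleotide synthesis given for set 1. Named genes farther along that chromosome were not looked for, so others may lie on it too.

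Over both steady-state sets together, with the set as a block, 649 of 14639 genes passed limma's test, 294 higher and 355 lower in Mycl KO cells, and 11 of them by at least 1.5-fold. Ribosome biogenesis genes fell in 19 of 60 cases and in 30 when adjusted over the list alone (median -0.15, camera adjusted p = 1.73e-24), with Wdr75 at -0.44 ± 0.05 and Rpf2, a factor of the large subunit, at -0.41 ± 0.04. MYC target core genes fell in 16 of 54 cases, 28 over the list alone (camera adjusted p = 1.06e-15), with Nip7 at -0.42 ± 0.06 and Nolc1 at -0.34 ± 0.05. Aminoacyl-tRNA synthetases fell in 6 of 18 cases, 10 over the list alone (camera adjusted p = 5.92e-10), with Tars at -0.38 ± 0.06. Cytosolic ribosomal proteins fell in 11 of 53 cases, 28 over the list alone (camera adjusted p = 2.15e-19), with Rpl14 at -0.29 ± 0.06. The adjusted p of these 4 lists was 0.0915, 0.106, 0.0915 and 0.106 with an estimated correlation. Maturation genes rose in 11 of 40 cases and in 23 when adjusted over the list alone (median 0.21, camera adjusted p = 5.92e-10; adjusted p = 0.114 with an estimated correlation), with Tnf at 0.72 ± 0.13 and the cytokine signalling inhibitor Socs2 at 0.56 ± 0.14. Of 27 cDC1 identity genes 7 rose, 13 rises and 1 fall when adjusted over the list alone (camera adjusted p = 2.68e-06; adjusted p = 0.114 with an estimated correlation), with the RNA sensor Tlr3 and Gcsam at 0.27 each. Cell cycle genes held 0 calls of 44 in limma's test by either adjustment (median -0.01, camera adjusted p = 0.561).

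Camera also called markers of other cells over both sets together, although their list scores differed little in set 1. There the mean scores of KO and heterozygous cells were 0.778 and 0.764 for plasmacytoid and -0.409 and -0.409 for B cell markers. For T and NK cell markers they were -0.898 and -0.882, lower in KO cells. The calls below are those of the pooled fit. Plasmacytoid markers (2 rises of 11, 3 rises and 1 fall over the list alone, median 0.13, camera adjusted p = 0.0320) lay higher. So did B cell markers (2 rises and 1 fall of 11 by either adjustment, median 0.08, 0.0394) and T and NK cell markers (0 of 13, 1 rise over the list alone, median 0.09, 0.0284). Their adjusted p was 0.163, 0.163 and 0.313 with an estimated correlation. In set 2, leaving out KO library 4 or 5 or WT library 2 ended all 3 calls, KO library 3 the plasmacytoid and T and NK calls, WT library 1 the T and NK call, and KO library 1 or WT library 5 the B cell call. The B cell call was also lost without KO library 2 or 3 or heterozygous library 1 or 2 of set 1. Immediate early genes rose in 4 of 25 cases, 6 over the list alone (median 0.10, camera adjusted p = 6.21e-05; adjusted p = 0.177 with an estimated correlation).

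Translation factors fell in 4 of 30 cases over both sets, 14 over the list alone (median -0.11, camera adjusted p = 7.67e-11), and nucleotide synthesis genes in 4 of 22 by either adjustment (median -0.07, 1.59e-05). Oxidative phosphorylation genes fell in 3 of 48 cases, 8 over the list alone (median -0.06, 3.76e-07), and mitochondrial translation genes in 1 of 39, 4 over the list alone (median -0.06, 2.19e-05). Their adjusted p was 0.0915, 0.163, 0.336 and 0.336 with an estimated correlation. Interferon genes (1 rise of 39 by either adjustment, median 0.06, camera adjusted p = 0.0284), antigen presentation genes (2 rises of 24, 3 rises and 1 fall over the list alone, median 0.04, 0.0110) and cholesterol synthesis genes (0 of 20 by either adjustment, median 0.06, 0.0152) lay higher. Their adjusted p was 0.464, 0.309 and 0.395 with an estimated correlation. The interferon call was lost without heterozygous library 5 of set 1 or KO library 3 or 5 or WT library 2 of set 2. The antigen presentation call was lost without heterozygous library 5 of set 1, and the cholesterol call without KO library 2 of set 2. Without KO library 2 of set 1 the nucleotide median was -0.05, without KO library 4 of set 1 the cholesterol median was 0.09, and without KO library 3 of set 2 the antigen presentation median was 0.07.

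Among single genes of both sets together, Ccnd2 (0.75 ± 0.12), the Src family kinase Fgr (0.65 ± 0.10), the thrombin receptor family member F2rl2 (0.63 ± 0.09), Myc (0.62 ± 0.15) and Scp2 (0.56 ± 0.11) rose. Adgrf5 (-1.02 ± 0.16), Ndufs5 (-0.91 ± 0.11), Cd14 (-0.74 ± 0.18), Ms4a1 (-0.63 ± 0.09) and Lmna, a lamin of the nuclear envelope (-0.50 ± 0.10), fell. Their adjusted p ranged from 9.14e-05 to 0.0219. Myc and Cd14 were among the genes whose KO effect differed between the sets, by 1.19 and -1.45 (set 2 minus set 1). Their pooled values therefore average unlike effects and describe neither set. Of the 649 genes, 45.3% were higher, against 33.5% of 618 genes after centring on array medians, and the count was 119 with all 8 groups in 1 fit.

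The Mycl KO effect differed between the steady-state sets in 148 of 14639 genes, 111 of them with a more positive value in set 2 and 37 with a more negative one. The difference was 1.19 ± 0.18 for Myc (adjusted p = 0.00324), which was at -0.01 ± 0.13 in set 1. It was 1.36 ± 0.30 for Klrd1, 1.24 ± 0.25 for Emb, 1.07 ± 0.20 for Cd226, 0.71 ± 0.10 for Bcl2, -1.45 ± 0.18 for Cd14 and -1.15 ± 0.11 for Mycl. The KO effect on cell cycle genes was more positive in set 2 in 42 of 44 cases. Of these 3 passed over all genes and 17 when adjusted over the list alone (median 0.31, camera adjusted p = 3.4e-11; adjusted p = 0.617 with an estimated correlation), with the replication licensing factor Cdc6 at 0.66 ± 0.13 and E2f8 at 0.59 ± 0.14. Cholesterol synthesis genes differed in 0 of 20 cases over all genes and in 2 over the list alone (median 0.21, camera adjusted p = 0.000788; adjusted p = 0.617 with an estimated correlation). The KO effect was also more positive in set 2 for MYC target core genes (2 of 54 past the test, 5 over the list alone, median 0.14, camera adjusted p = 0.000454). The same held for ribosome biogenesis (2 of 60, with 3 more positive and 1 more negative over the list alone, median 0.09, 0.00233) and nucleotide synthesis (1 of 22, 4 over the list alone, median 0.12, 0.0114). It was more negative for cytosolic ribosomal proteins (0 of 53, 1 over the list alone, median -0.09, camera adjusted p = 2.35e-05) and immediate early genes (1 in each direction of 25, 2 more positive and 6 more negative over the list alone, median -0.13, 0.00433). The adjusted p was 0.699 for ribosome biogenesis and 0.617 for the other 4 lists with an estimated correlation. Without KO library 2 of set 1 the calls of ribosome biogenesis and nucleotide synthesis were lost (camera adjusted p = 0.130 each), and without KO library 1 of set 2 that of immediate early genes (0.0649). Controls were heterozygous in set 1 and WT in set 2, so the control genotype and the set cannot be told apart. The count of 148 was 62, 84 and 31 without KO library 1, 2 or 3 of set 1, and 95, 74 and 90 without heterozygous library 2, 3 or 5. It was 317 and 48 without KO library 1 or 5 of set 2, and 77, 67, 90 and 233 without WT library 1, 2, 3 or 5. Of the 148 genes 75% were more positive in set 2, against 55.1% of 118 after quantile normalization of all arrays, and the count was 15 with all 8 groups in 1 fit and 584 with array weights.

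Across the 13508 genes tested in both sets, without Mycl, the fold changes of sets 1 and 2 had a Pearson r of 0.161 and a Spearman rho of 0.0865; genes are not independent replicates. Without KO library 1 of set 2, r was 0.0946. Of the genes called in set 2, 852 were also tested in set 1 and 64.4% had the same sign there. The 524 that rose in set 2 had a median of 0.31 in set 2 and 0.02 in set 1 (57.4% with the same sign), and the 328 that fell had medians of -0.31 and -0.10 (75.6%).

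Under poly IC, in set 3, no named gene passed limma's test between Mycl KO and WT cells (0 of 14033, with 1992 at an unadjusted p under 0.05 and a lowest adjusted p of 0.106). Mycl itself was at -2.96 ± 0.54 (adjusted p = 0.150) with KO library 3, and at -3.56 (adjusted p = 3.2e-05) without it. The gene with the lowest p was Adam23, a maturation list member, at -0.72 ± 0.09, and Slc2a1 was at 0.47 ± 0.08 (adjusted p = 0.150) and Myc at 0.40 ± 0.10 (adjusted p = 0.229). All 41 type I interferon genes lay above 0 in KO cells (median 0.85, camera adjusted p = 1.14e-11; adjusted p = 0.406 with an estimated correlation). So did 40 of 42 maturation genes, of which 1 was higher and 1 lower when adjusted over the list alone (median 0.52, camera adjusted p = 9.9e-10; adjusted p = 0.406 with an estimated correlation). WT libraries 1 and 4 had low interferon scores, 2.19 and 3.14 against 4.54 to 4.79 in the other 3 WT and 4.56 to 4.93 in the 5 KO libraries. Dixon's test marked neither, but it looks for a single library standing apart, and libraries that lie low together can hide each other from it. Without both libraries the medians of these lists were 0.08 and 0.05, and the camera call of the second was lost (adjusted p = 0.180).

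Ribosome and translation genes lay lower in the KO cells of set 3. Of 60 ribosome biogenesis genes 59 lay below 0 (median -0.49, camera adjusted p = 1.08e-16; adjusted p = 0.406 with an estimated correlation). Of 54 MYC target core genes 46 did (median -0.39, camera adjusted p = 7.25e-09; adjusted p = 0.406 with an estimated correlation). Of 18 aminoacyl-tRNA synthetases 17 did (median -0.39, camera adjusted p = 5.74e-09; adjusted p = 0.399 with an estimated correlation). Tars, for threonine, was at -0.93 ± 0.21 (adjusted p = 0.217). Adjusted over the list alone, 0, 0 and 12 of them were lower. WT libraries 1 and 4 also had the highest ribosome biogenesis scores, 2.40 and 2.17 against 1.36 to 1.45 in the other WT libraries, and without them the medians of the 3 lists were -0.11, -0.08 and -0.18. Translation factors had a median of -0.26 (camera adjusted p = 5.08e-08), nucleotide synthesis genes of -0.36 (0.000133), cytosolic ribosomal proteins of -0.14 (1.28e-12) and cDC1 identity genes of -0.18 (0.0364), with 0 members past either adjustment and an adjusted p of 0.406, 0.452, 0.406 and 0.596 with an estimated correlation. Without WT libraries 1 and 4 these medians were -0.11, -0.03, -0.10 and -0.00548, and the camera calls of nucleotide synthesis (adjusted p = 0.127) and cDC1 identity (0.836) were lost. That of cDC1 identity was also lost without WT library 1 or 4 or KO library 1 or 3 alone (adjusted p = 0.0626, 0.160, 0.103 and 0.0921). Immediate early genes (7 higher of 25 when adjusted over the list alone, median 0.20, camera adjusted p = 2.28e-05), T and NK cell markers (2 of 11, median 0.18, 0.00236) and cDC2 markers (2 of 11, median 0.18, 0.00288) lay higher, with an adjusted p of 0.136 with an estimated correlation in each. The T and NK median was 0.11 without KO library 4, and that of cDC2 markers was 0.11 without WT libraries 1 and 4. Plasmacytoid markers (8 of 10 above 0, median 0.17, camera adjusted p = 0.0249) and apoptosis genes (17 of 21, median 0.22, 0.00354) lay higher as well. Mitochondrial translation (31 of 39 below 0, median -0.15, 0.00236), cell cycle (34 of 44, median -0.08, 0.0376) and oxidative phosphorylation genes (35 of 48, median -0.08, 0.0438) lay lower. These 5 lists had 0 members past either adjustment and an adjusted p of 0.215, 0.406, 0.622, 0.689 and 0.700 with an estimated correlation. Without WT libraries 1 and 4 the calls of the last 4 were lost (camera adjusted p = 0.836, 0.836, 0.408 and 0.289). Those of cell cycle and oxidative phosphorylation genes were also lost without WT library 1 or 4 or KO library 2 or 5 alone, and the latter without KO library 1 or 4. Without KO library 3 both medians were -0.14, and without WT library 3 that of the cell cycle was -0.13. Gzmb of the T and NK list, which encodes granzyme B, was at 1.08 ± 0.16 (adjusted p = 0.121).

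**Figure D3:**
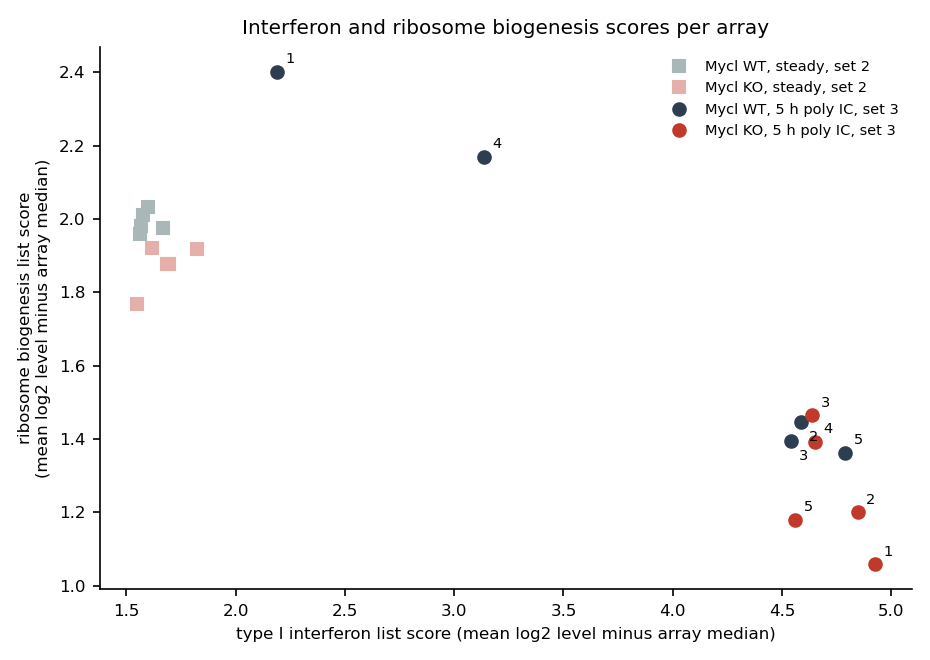
Mean log2 level, minus the array median, of the type I interferon genes (x) and the ribosome biogenesis genes (y) on each array of set 3, numbered by replicate, with the arrays of set 2, which were normalized separately. WT libraries 1 and 4 of set 3 lie at interferon scores of 2.19 and 3.14 and all other libraries of set 3 at 4.54 to 4.93.

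The count of 0 genes in set 3 depended on which libraries entered and on how their spread was pooled. It was 11 (10 higher, 1 lower) without WT libraries 1 and 4 and 63 (39 higher, 24 lower) without these and KO library 3, alternatives that were chosen after seeing the data, and 1910 with all 8 groups in 1 fit. It was 1 without KO library 2 or WT library 5 and 2 without KO library 3. The difference between the Mycl KO effects under poly IC and at steady state, a test in which the offset between the sets cancels, passed for 3 of 14665 genes. Adgrf5 (1.45 ± 0.24, adjusted p = 0.0316) and Gzmb (1.14 ± 0.18, adjusted p = 0.0218) were more positive in set 3 and Adam23 (-0.85 ± 0.11, adjusted p = 0.00497) more negative. Adgrf5 was at 4.17 in WT and KO cells of set 3, below the filter level there, so a fall could not show and its difference is no sign of another KO effect. Gzmb lay below the filter level in WT and KO cells of set 2 (4.34 in KO cells), so its difference rests on set 3. Sets 2 and 3 also differ in the sex of the mice, so poly IC cannot be told apart from sex and set in these differences. Myc had a difference of -0.78 ± 0.16 (adjusted p = 0.0789). The interferon list differed by a median of 0.73 (camera adjusted p = 3.52e-09) and ribosome biogenesis by -0.39 (camera adjusted p = 3.52e-09), each at an adjusted p = 0.662 with an estimated correlation. Without WT libraries 1 and 4 of set 3 these medians were -0.03 and -0.03, and neither list passed camera (adjusted p = 0.939 and 0.650). Camera also called more negative values in set 3 for MYC target core (median -0.31), aminoacyl-tRNA synthetases (-0.29), nucleotide synthesis (-0.25), cell cycle (-0.21), cDC1 identity (-0.21) and cholesterol synthesis genes (-0.22). It called more positive ones for maturation (0.29), ATF4 stress (0.08) and chaperone genes (median 0.00084, mean 0.20). Camera's adjusted p for these 9 lists ranged from 1.1e-05 to 0.0208, and it was 0.662 for each with an estimated correlation. Without WT libraries 1 and 4 of set 3 the calls of cholesterol synthesis, ATF4 stress and chaperone genes were kept and the other 6 were lost. Without KO library 3 of set 3 as well, 4 of all 11 list calls were kept. Among these were aminoacyl-tRNA synthetases (camera adjusted p = 0.000337), cell cycle (0.000353) and cholesterol synthesis genes (0.000353). The chaperone call was lost without WT library 1 of set 2, WT library 3 of set 3 or KO library 3 of set 3, and the ATF4 median was 0.13 without KO library 1 of set 3. The count of 3 was 41 without WT libraries 1 and 4 of set 3. It was 1 without WT library 2 or 4 or KO library 2 of set 3, or without KO library 2, 3 or 5 or WT library 1 or 5 of set 2. It was 14, 10 and 30 without WT library 1, 3 or 5 of set 3, 9 and 5 without KO library 1 or 4 of set 3, and 11 without KO library 4 of set 2.

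Fold changes of sets 2 and 3 had a Pearson r of 0.30 and a Spearman rho of 0.229 across 13444 genes without Mycl, and 602 of the 837 genes called in set 2 and tested in both had the same sign in set 3 (71.9%).

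Levels under poly IC and at steady state come from sets that were normalized separately, so their differences, each relative to the array medians, are untested and hold any offset between the sets. In WT cells, interferon-induced transcripts were higher under poly IC, such as Ifit1 at 9.26 ± 2.39 (SD) against 4.43 ± 0.10, a difference of 4.92 from a steady level below the filter, and the median of the interferon list was 2.05 higher. In Mycl KO cells Ifit1 was at 11.2 ± 0.26 against 4.51 ± 0.11 and the list median was 2.92 higher. Maturation genes were higher by a median of 1.00 in WT and 1.26 in KO cells, and immediate early genes lower by medians of -0.79 and -0.70. Dusp6, a phosphatase of ERK kinases, was lower in WT (-2.51) and KO cells (-3.46), as was the lysozyme Lyz2 (-2.37 and -3.09). A difference above 2 on the log2 scale was found for 85 genes upwards and 16 downwards in WT, and for 202 and 50 in KO cells, where libraries 1 and 4 are part of the WT mean. Differences in WT and KO cells correlated across 14074 genes (r = 0.950), and shared offsets between the sets enter both. Xist, transcribed from the inactive X chromosome, was at 10.6 in WT and 10.7 in KO cells of set 2 and at 4.25 in either genotype of set 3, so the sex of the mice also differed between the sets.

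In the Mxd1 set, 18 h after poly IC, 10 of 14080 genes passed limma's test between libraries labelled Mxd1 KO and WT libraries, 4 higher and 6 lower (n = 3 each). Asns, which makes asparagine, rose by 2.42 ± 0.20 (adjusted p = 0.00521), the heme-binding protein Hebp1 by 1.60 ± 0.08 (adjusted p = 0.000372). The lectin langerin, Cd207, rose by 1.18 ± 0.13 (adjusted p = 0.0272) and the endocytic protein Snx9 by 0.90 ± 0.11 (adjusted p = 0.0389). Lad1, a filament-anchoring protein, fell by 1.69 ± 0.12, the heat shock protein Hspa1a by 1.56 ± 0.19, the costimulatory ligand Tnfsf9 (4-1BBL) by 1.21 ± 0.13. The macrophage transcription factor Spic fell by 1.14 ± 0.11, the noncoding RNA Gas5 by 0.79 ± 0.09 and Pdcd1lg2 (PD-L2) by 0.68 ± 0.09, with adjusted p from 0.00199 to 0.0490 over these 6 genes. Cd207 lies within 40 tested genes of Mxd1 on its chromosome. Called genes farther along that chromosome were not looked for, so other calls may lie on it too. The count of 10 was 568 (426 higher, 142 lower) without WT library 2, 4 without WT library 1 or KO library 3, and 3 without KO library 1 or 2. It was 235 with all 8 groups in 1 fit.

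Genes of ribosome biogenesis, translation and the cell cycle lay higher in the libraries labelled Mxd1 KO, whose Mxd1 level does not support that label. All 60 ribosome biogenesis genes lay above 0 (median 0.25, camera adjusted p = 4.71e-13), as did 50 of 54 MYC target core genes (median 0.20, camera adjusted p = 1.88e-07). So did 28 of 30 translation factors (median 0.22, camera adjusted p = 2.95e-06) and 17 of 18 aminoacyl-tRNA synthetases (median 0.27, camera adjusted p = 4.51e-06). In these 4 lists 0 members passed either adjustment in limma's test. An example is Nop58, a core protein of box C/D particles, at 0.71 ± 0.18 (adjusted p = 0.183). Cell cycle genes lay above 0 in 43 of 44 cases, 0 of them past limma's test over all genes and 25 when adjusted over the list alone (median 0.41, camera adjusted p = 1.06e-18), with the mitotic checkpoint kinase Bub1b at 0.58 ± 0.10 (adjusted p = 0.101). Without WT library 1 the medians of the first 4 lists were 0.14, 0.12, 0.10 and 0.16. With an estimated correlation the adjusted p was 0.421 for translation factors and 0.419 for the other 4 lists. Cytosolic ribosomal proteins had a median of 0.01 (camera adjusted p = 0.592), which was -0.06 without WT library 1 (camera adjusted p = 0.0299) and 0.09 without WT library 3. Nucleotide synthesis (19 of 22 above 0, median 0.13, camera adjusted p = 0.00779), oxidative phosphorylation (44 of 48, median 0.13, 0.000731) and mitochondrial translation genes (34 of 39, median 0.12, 0.00487) lay higher. So did glycolysis genes (13 of 16, median 0.12, 0.00201) and chaperones (18 of 23, median 0.23, 0.00487), although Hspa1a of the latter fell. Over the list alone, 1 nucleotide gene was higher and 1 lower, 5 chaperones were higher and 2 lower, and the other 3 lists held 0 calls. The adjusted p was 0.496, 0.650, 0.616, 0.419 and 0.419 with an estimated correlation. Without WT library 1 the first 3 calls were lost (camera adjusted p = 0.208, 0.783 and 0.723), and without WT library 3 these medians were 0.23, 0.22 and 0.23.

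Maturation genes lay lower in the libraries labelled Mxd1 KO, with 2 falls, Tnfsf9 and Pdcd1lg2, among 39 and 10 falls when adjusted over the list alone (median -0.20, camera adjusted p = 3.84e-08; adjusted p = 0.419 with an estimated correlation). Interferon genes had a median of -0.00474 (camera adjusted p = 0.403). Immediate early genes (5 lower of 25 when adjusted over the list alone, median -0.15, camera adjusted p = 0.000264), cholesterol synthesis genes (2 lower of 20, median -0.12, 0.00434), T and NK cell markers (1 lower of 10, median -0.15, 0.00354) and cDC2 markers (1 lower of 9, median -0.16, 0.0109) lay lower, and cDC1 identity genes (0 of 27, median 0.19, 0.000612) higher. Their adjusted p was 0.419, 0.419, 0.419, 0.419 and 0.448 with an estimated correlation. Without WT library 1 the medians of maturation, cholesterol synthesis and cDC1 identity were -0.11, -0.05 and 0.07. Without WT library 3 that of cholesterol synthesis was -0.19, and without WT library 2 the call of cDC2 markers was lost (camera adjusted p = 0.0711). Plasmacytoid markers lay lower too (9 of 11 below 0, 1 lower over the list alone, median -0.05, camera adjusted p = 0.0470; adjusted p = 0.419 with an estimated correlation). Without WT library 1 that median was -0.12, and without WT library 2 or 3 or KO library 1 or 3 the call was lost. The ATF4 stress response held 1 rise, Asns, of 19 genes, 2 rises and 1 fall when adjusted over the list alone, and did not pass camera (adjusted p = 0.666). Ciita, the activator of MHC class II genes, was at 1.06 ± 0.15 (adjusted p = 0.0843). Across 13515 genes without Mycl, the fold changes of set 3 and the Mxd1 set had a Pearson r of -0.453 and a Spearman rho of -0.457. Without WT libraries 1 and 4 of set 3, r was -0.137.

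**Figure D4:**
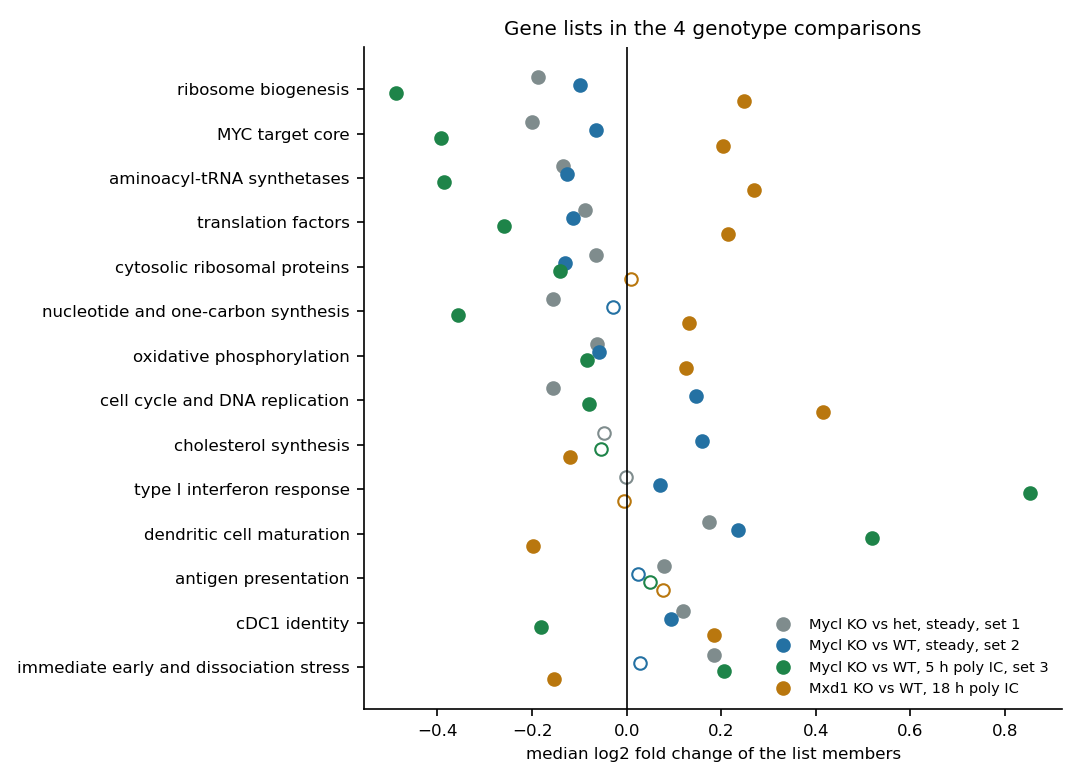
Median log2 fold change (KO minus control) of the members of 14 gene lists in the 4 genotype comparisons, filled where camera's adjusted p at the preset correlation was under 0.05; none of these calls was kept with an estimated correlation. Ribosome biogenesis lies at -0.19, -0.10 and -0.49 in the Mycl KO groups of sets 1, 2 and 3 and at 0.25 in the libraries labelled Mxd1 KO. In set 3 it was at -0.11 without WT libraries 1 and 4, and the KO group there includes library 3 with high Mycl.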

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

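The tests of the patterns in this part were chosen only after the result was seen, except that of a single wrong label for KO library 3, whose prediction was written before its result was seen.

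Library values standing apart from their group were found in 12 of 174 groups tested, and chance alone would mark about 1 in 20 groups. In set 1, heterozygous library 5 stood apart with Mycl at 9.65, an antigen presentation score of 4.77 and a cDC1 identity score of 4.19. In set 2, WT library 1 stood apart in chaperones (4.27) and WT library 4 in erythroid markers (-0.791). Under poly IC, WT library 1 stood apart in antigen presentation (5.31), KO library 2 in maturation genes (4.13) and KO library 5 in B cell markers (-0.279). KO library 3 stood apart in Mycl (8.87), cytosolic ribosomal proteins (5.78), oxidative phosphorylation (4.10) and mitochondrial translation (1.92).

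KO library 3 of set 3 carries Mycl at 8.87, close to the WT libraries. A swap with a WT library is argued against, because the lowest WT level of Mycl is 9.03 (9.025) while the other KO libraries reach at most 6.14. A single wrong label stays open. Over the 64 genes changed at least 1.5-fold in set 2, its signed score of 0.334 lies just below the 0.335 to 0.518 of the other KO libraries and above the -0.30 to 0.25 of the WT libraries. Ndufs5, near Mycl, was at 7.96 as in WT cells (7.94 ± 0.26) and not as in the other KO libraries (6.76 ± 0.31), Fhl3 was at 5.48 as in WT cells (5.48 ± 0.29; other KO 5.95 ± 0.26), and Thrap3 was at 9.75 as in the other KO libraries (9.66 ± 0.11; WT 10.19 ± 0.08).

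WT libraries 1 and 4 of set 3 have low interferon-induced transcripts. That they were untreated stays open. The lower of their interferon scores, 2.19, lies 0.525 above the highest steady-state WT score of 1.67, but the sets were normalized separately and differ in sex, and the PBS injections of the protocol cannot be tied to any sample. A smaller response to poly IC fits, as an absent response would, since outside the interferon list their deviations ran against the poly IC difference of the KO libraries with r = -0.729 and -0.627. Dose, time and the sort were not tested.

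Set 2 had 861 changed genes and set 1 had 3, with markers of other cells among the former. Whether cells of another type entered the KO sorts stays open. That 4 lists of another cell type hold rises and falls together cannot decide it, since cDC1 could lower some markers themselves. T and NK cell markers held 2 rises and 0 falls. Natural killer cells stay open as well. The upper 95% bound of Nkg7 (0.391) lies below the lower bound of Klrd1 (0.60). But Nkg7 was dim, at 5.06 in WT and 5.21 in KO cells, so a rise may not show in full. Of the same list, Tbx21 rose by 0.39 ± 0.07 while Prf1 was at -0.07 ± 0.07. The heterozygous controls of set 1 stay open as a reason. The slope of set 1 on set 2 differences over genes called in set 2 was 0.153, and set and control genotype change together.

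The difference between sets 1 and 2 in the Mycl KO effect, 148 genes, held Mycl (-1.15), Klrd1 (1.36), Emb (1.24), Myc (1.19), Cd226 (1.07), Emp1 (0.91), Elavl4 (0.90), Ms4a6c (0.87), Rasgrp2 (0.85), Cd14 (-1.45), Arih2 (-0.78), Tssc4 (-0.72), Ccrl2 (-0.69), Chac1 (-0.69), Ptgis (-0.67) and Efcc1 (-0.66). Elavl4 lay below the filter level in the control cells of either set. The difference between sets 3 and 2, 3 genes, held Adgrf5 (1.45), Gzmb (1.14) and Adam23 (-0.85). Adgrf5 lay below the filter level in set 3, where a fall could not show, and Gzmb lay below it in set 2. Clusters without a single gene symbol, which the gene tests left out, passed limma's test in set 2 for 63 of 7891 (35 higher, 28 lower). They passed in set 3 for 2 of 8066 (both lower), with 0 in set 1 (727 at an unadjusted p under 0.05) and 0 in the Mxd1 set (977).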

How the results depend on the processing

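The number of genes past the threshold depends on how the spread of values is estimated and on single arrays more than the directions do. In set 1 the 3 genes became 1 with a 1.5-fold minimum, 5 with a filter at the 50th percentile, 6 after quantile normalization, 141 with array weights and 1 with the replicate number as a block (Wdr75 adjusted p = 0.190, Abce1 0.270). In set 2 the 861 became 65 with the 1.5-fold minimum and 358 with all 8 groups in 1 fit. In set 3 the 0 became 1 without a filter, 1910 with all groups, 72 with weights and 1 with the block, and Mycl was at -2.96 with all groups and -3.02 with weights. Chosen after seeing the data, leaving out WT libraries 1 and 4 gave 11 genes, leaving out KO library 3 as well gave 63 (Mycl -3.36), and an interferon covariate gave 8. Without WT libraries 1 and 4, the medians of oxidative phosphorylation, mitochondrial translation and cell cycle genes turned to 0.037, 0.027 and 0.054. Without all 3 libraries that of cDC1 identity turned to 0.028. With the covariate those of oxidative phosphorylation, mitochondrial translation, cell cycle and interferon genes turned to 0.036, 0.033, 0.055 and -0.0056.

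In the Mxd1 set the 10 genes became 235 with all groups, 18 with weights and 16 with the block, and cytosolic ribosomal proteins turned to -0.056 without WT replicate 1 and were at 0.092 without WT replicate 3. For the difference between poly IC and steady state the 3 genes became 6 at the 50th percentile, 181 with all groups, 9 with a trended robust prior, 74 with weights, 41 without WT libraries 1 and 4 (interferon -0.034, maturation -0.13) and 54 without all 3 (maturation -0.104). With the block it became 2 other genes, with an adjusted p of 0.0591 for Adgrf5, 0.0716 for Gzmb and 0.0538 for Adam23. Between sets 1 and 2 the 148 became 44 with the 1.5-fold minimum, 15 with all groups (Mycl -1.15), 584 with weights and 30 with the block. Over both sets the 649 became 11 with the 1.5-fold minimum and 119 with all groups. Of the named genes past the threshold, all groups in 1 fit kept 35 of 57 in set 2, 8 of 10 in the Mxd1 set, 9 of 31 for the difference between sets 1 and 2 and 23 of 49 over both sets. The correlation of sets 1 and 2 was 0.086 as Spearman's rho, 0.118 without a filter and 0.210 at the 50th percentile. That of sets 2 and 3 was 0.229, 0.269 and 0.335, and 0.260 without WT libraries 1 and 4. That of set 3 and the Mxd1 set was -0.137 without WT libraries 1 and 4 and -0.202 without all 3. Leaving out 1 array at a time gave 1 to 7 genes in set 1, 408 to 1012 in set 2, 0 to 2 in set 3, 3 to 568 in the Mxd1 set, 1 to 30 and 31 to 317 for the differences and 433 to 854 over both sets. Mycl in set 3 ranged from -3.56 (without KO library 3) to -2.72 (without KO library 4). The correlations ranged from 0.095 to 0.224, from 0.273 to 0.337 and from -0.488 to -0.318. Centring on control features was not run. The replicate numbers do not pair libraries (r of same-number pairs -0.40 to 0.35).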

Other observations

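The tests of the signature and of neighbouring genes in this part were chosen only after the result was seen, while the splits of the samples were planned.

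Markers of neutrophils and erythroid cells were higher in the cDC1 sorts under poly IC than at steady state, untested because the sets were normalized separately. All 9 neutrophil markers were higher in WT cells (median difference 2.31) and all 10 in KO cells (2.41), with the granule protein Ngp at 8.55 ± 1.04 (SD) against 4.36 ± 0.06, below the filter level, in KO cells. Erythroid markers differed by 0.53 and 0.92. The Mxd1 set, 18 h after poly IC, did not share these high levels. Its neutrophil scores were -1.14 in WT and -0.96 in libraries labelled Mxd1 KO. In WT and KO cells they were 0.31 and 0.51 in set 3 and -1.18 and -1.20 in set 2. Erythroid scores, in the same order, were -0.72 and -0.66, then 0.02 and -0.09, then -0.66 and -0.73. Mxd1 was at 9.94 ± 0.88 under poly IC and 7.91 ± 0.28 at steady state in WT cells, and at 10.60 ± 0.10 and 8.19 ± 0.27 in KO cells, while Myc was at 6.65 ± 0.12 and 7.54 ± 0.25 in WT cells.

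Over the 64 genes that changed at least 1.5-fold in set 2, without Mycl, the signed score was 0.408 ± 0.080 (SD) in KO and 0 ± 0.26 in WT libraries of set 3 (exact permutation p = 0.00794, 252 ways). The score fits a recurrence of the set 2 changes under poly IC, with WT libraries 1 and 4 at -0.27 and -0.30. Ndufs5, near Mycl, was among the 64 genes, and no score without the genes near Mycl was made. Without these libraries the difference was 0.220 and not 0.408 (exact permutation p = 0.0179, 56 ways). In set 1 the score was 0.098 ± 0.049 in KO libraries (exact permutation p = 0.0635, 126 ways), which leaves the recurrence open there.

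Of the genes near Mycl, 9 within 40 tested genes on either side changed in set 2 (Slc2a1, Svbp, Ppcs, Ctps, Rlf, Cap1, Ndufs5, Fhl3 and Thrap3). As many were held by 6.61% of 12400 windows, whose median was 5. Near Mxd1, 1 gene changed in the Mxd1 set, Cd207, and 5.25% of 12466 windows held as many. With 10 genes called and at most 1 in any window, that share was nearly fixed in advance and decides nothing. DNA flanking either mutation could differ between the groups. The value of 6.61% leaves that open for Mycl, and the windows cannot decide it for Mxd1. Windows count calls only, so the size of changes and genes farther along either chromosome were not weighed.

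Only the real 1 of 100 splits of the samples gave as many as the 3 genes of set 1, and the highest other split gave 0. Mycl, the mutated gene, is among the 3, so chance is not excluded for Wdr75 and Abce1. Splits cannot tell the genotype from anything else that differs between the groups. Chance is unlikely, though not excluded, as the source of the count of 861 genes of set 2 (1 of 100, highest other split 186). The same holds for the count of 649 genes over both sets (1 of 100, highest other split 320). That other split kept the labels of set 2 and mixed those of set 1, so the splits do not show that both sets share these changes. Splits also break the KO effect within each set, so for a difference between KO effects they do not show whether chance can be excluded. As many as the 3 genes of the difference between sets 3 and 2 were given by 1 of 100 splits (highest other split 1), and as many as the 148 of the difference between sets 1 and 2 by 2 of 100. The highest other split there, 274, kept the labels of set 2 and mixed those of set 1. For the 0 genes of set 3 every split gives as many (100 of 100, highest other split 0), so the splits say nothing about chance, and for the 10 genes of the Mxd1 set the 10 splits are too few (1, highest other split 0). For correlations across genes, which are not independent replicates, only the real 1 of 100 splits gave as much for sets 2 and 3 (r = 0.30, highest other split 0.291). That margin is smaller than the move to 0.273 when 1 array is left out, so chance is not firmly excluded there. It is not excluded for sets 1 and 2 (r = 0.161, 35 of 100, highest other split 0.361) or for set 3 and the Mxd1 set (r = -0.453, 23 of 100, highest other split 0.510).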
